A study of Mus musculus with 2 samples.

How the data were processed

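H3K4me1 ChIP-seq had been carried out by the authors on intestine of mouse embryos at embryonic day 14.5, in 2 biological replicates of 24 and 34 pooled embryos, the second with 2 technical replicates, per the labels. The labels give a single group of mixed-sex tissue, the strain B6NTac;B6NCrl/Lap and the genome build mm10. The aligner, the peak caller and its thresholds are not given in the sources used here. Per the deposited descriptions, the authors called peaks on each replicate against control libraries, with 2 control files named for replicate 1 and 1 for replicate 2, called peaks on both replicates pooled, and derived a list of replicated peaks from these 3 lists.

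The lists are in narrowPeak format. Column 7 is the authors' fold enrichment of ChIP over control, a linear ratio at the peak's point source, and the deposited columns 8 and 9 are the −log10 of the p value and of the q value. These meanings follow from the column order of the format and from the values. All lists end near a p value of 0.01, and a q value of 0.01 or lower is given for 66.8% of the peaks of replicate 1, 31.2% of replicate 2, 78.04% of the pooled list and 93.49% of the replicated list. Each replicated peak is an entry of the pooled list. Of the 83483, 53716 (64.3%) overlapped a peak of both replicates and 29767 (35.7%) lacked a peak of at least 1 of them, so the list's rule is not a plain overlap with both lists. Read numbers are not in the lists, and the depth per sample is therefore unknown. Intervals for shares of peaks are 95% Wilson intervals and cover counting error only: 33.1% to 33.5% for the shared peaks of replicate 1 and 79.7% to 80.2% for those of replicate 2. The spread over 2 replicates is the error given for other values.

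Chromosome names and lengths of the lists were checked against the GRCm38 sequence, and no peak lay past a chromosome's end or on Y. Genes were those of GENCODE release M21 on the autosomes and X, 53843 in all and 21728 protein-coding. The 5′ end of a gene is its outermost annotated one. Interval arithmetic, shuffles and motif scans were written in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9. A peak counted as shared when it overlapped the other list by at least 1 bp. Expected values came from 100 shuffles of peaks within their chromosomes outside assembly gaps of 100 bp or more. Coverage of a gene was the share of the 20-kb window around its 5′ end (10 kb each side) that peaks covered. Gene lists were tested on the median of that share in replicated peaks against 10000 random lists of the same size, two-sided, with Benjamini-Hochberg adjustment over 23 lists. The lists were gut epithelium, gut mesenchyme, smooth muscle and interstitial cells of Cajal, enteric nervous system, blood and lymphatic endothelium, blood cells, mesothelium, mature intestinal epithelial lineages, liver, pancreas, lung and stomach, forebrain, heart, skeletal muscle, germ cells, retina, housekeeping genes, Hox genes, olfactory receptors, and the Wnt, hedgehog, BMP and TGF-beta, and Notch pathways. All 390 entries of the 21 lists written as symbols matched the annotation. The classes of gut wall cells and of other organs were compared by 100000 permutations of the class over genes, two-sided. Domains were replicated peaks joined across gaps of up to 3 kb. Motifs were scanned on both strands in the 500 bp around the point source of replicated peaks over 1 kb from any 5′ end, against 100 draws of windows outside all peaks matched on chromosome and GC decile, with adjustment over 20 motifs.

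The lists, motifs, tests, thresholds and most alternatives were chosen before the data were examined. Genes named are the 10 protein-coding genes with the largest mean window share among those covered in both replicates and in the replicated list, and for each list up to 4 members with the largest mean and up to 3 members without a peak. Also named are genes over the 10 longest domains, the 10 replicated peaks with the largest fold, the 5 genes each way that differ most between replicates at equal numbers of peaks, and any Hox gene. Cdx2, Foxf1, Smad3, Irf1, the gene families, the X genes and the protocadherins other than Pcdhgc5 stand outside this rule and were named after their values were seen.

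The overlap, gene list, class comparison, motif and background steps were tested on simulated data. With 39.7% of 84066 peaks copied into a second list, the overlap step found 39.1% after the chance share was taken off. In the gene list test on 21728 genes, 0.5% of lists of 20 genes without an effect had a p under 0.05, and planted lists with 1, 2 and 4 extra peaks per gene were found in 48%, 96% and 100% of 50 cases. In the comparison of classes, run on 250 randomly drawn coding genes split into 2 sets, planted differences of 0, 2, 4 and 8 percentage points had a p under 0.05 in 4%, 52%, 94% and 100% of 50 cases. The motif scan found all sites that had been put into 25% of 4000 windows. The pileup and background behind each peak, used in the closing observations, were recovered from the fold and p values under a Poisson model, and a simulated background of 2.3 was found as 2.3.

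The alternatives were a q value of at most 0.01, a fold of at least 3, an overlap of 50% of the peak or of both peaks, equal numbers of peaks (84066 per replicate, by p value), peaks joined across 1 kb, start sites of 2 kb, any overlap with the start window, protein-coding genes only, and windows of 2 or 50 kb each side or the gene body with 5 kb. Random lists were also matched on quintile of CpG content, the ratio of observed to expected CpG within 500 bp of the 5′ end. Others were the pooled list, domain gaps of 1 or 10 kb and motif windows of 1000 bp. Further ones were background windows 5 to 10 kb from the peak, and each replicate left out. With equal numbers of peaks, window shares were means over the replicates. Pooled peaks overlapping both replicates, autosomal genes only and another draw of the random lists were added after the data were seen. Chromosome Y and unplaced sequences were left out of the gene tests because no peak lay on them.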

Results

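H3K4me1, the monomethylation of histone H3 at lysine 4 that marks enhancers and the flanks of promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the intestine of mouse embryos at embryonic day 14.5. The samples formed 1 group of 2 biological replicates, with tissue pooled from 24 embryos of mixed sex in replicate 1 and from 34 in replicate 2. No treatment, stage or tissue was contrasted, so the design allows a comparison between the replicates, and of both with gene annotation of the same genome build, GRCm38 (mm10). Replicate 1 listed 183305 peaks that covered 78.2 Mb (3.06% of the genome outside assembly gaps), with a median width of 307 bp. Replicate 2 listed 84066 peaks over 30.0 Mb (1.17%), with a median width of 281 bp. The authors' pooled list held 142116 peaks over 72.8 Mb, and their list of replicated peaks held 83483 over 56.3 Mb, with a median width of 524 bp. The lists give no read numbers, so the sequencing depth behind each value is unknown. Fold enrichments and p values of single peaks are the authors' own. They were used within a list only, except in the closing observations, where backgrounds and pileups recovered from them were compared between lists. At a q value of at most 0.01, replicate 1 kept 122473 peaks (66.8%) and replicate 2 kept 26222 (31.2%).

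The first comparison asked how far the replicates marked the same regions. Of replicate 1's peaks, 33.3% overlapped a peak of replicate 2 (61020 peaks), and 79.95% of replicate 2's peaks overlapped a peak of replicate 1 (67212 peaks). Shuffling the other list within chromosomes gave 2.77% and 5.94%, so the overlaps were 12.02 and 13.45 times those of shuffled peaks (one-sided permutation p = 0.0099 for each, the smallest that 100 shuffles can give). Peaks of the highest fold decile were shared most, at 80.1% in replicate 1 and 97.3% in replicate 2, against 15.1% and 75.2% in the lowest decile. In replicate 2 the share was smallest in deciles 2 and 3 from the bottom, at 67.6% and 67.7%. In base pairs the replicates shared 21.5 of the 86.8 Mb that either covered (24.8%). The share of replicate 1's peaks depended on the rule, with 50.9% at equal numbers of peaks, 18.4% at a q value of at most 0.01 and 13.99% at a reciprocal overlap of 50%. For replicate 2 the reciprocal rule gave 30.5%.

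Single genes differed between the replicates even when each list was limited to its 84066 most significant peaks. They were compared by the share of the 20-kb window centred on a gene's annotated 5′ end that peaks covered, called the window share here. It was 51.3% in replicate 1 and 24.7% in replicate 2 at Rcsd1 (chromosome 1, 165646516 to 165709757), the largest difference of the genes, at 26.6 percentage points. Kif21b, a kinesin motor (chromosome 1, 136131389 to 136177998), differed by 25.8 points, and Myrf, the myelin regulatory factor, by 25.7 points. Cdh3, which encodes P-cadherin, and Ager, the receptor for advanced glycation end products, followed at 23.9 points each. In the other direction Arfgap2, a GTPase-activating protein of Arf1, stood at 2.02% in replicate 1 and 12.6% in replicate 2, and Ptgis, the prostacyclin synthase, at 6.40% and 15.7%. 4930558K02Rik, Tulp2 and Ntmt1 were the remaining genes of that end. Equal numbers of peaks do not equalise covered bases. In the full lists the mean peak width was 427 bp in replicate 1 and 357 bp in replicate 2. The 10 genes with the largest mean window share were all higher in replicate 1 at equal numbers, by 3.65 to 25.8 points. A general excess of covered bases in replicate 1 therefore cannot be told apart here from differences of single genes. With 1 biological sample on each side of the comparison, none of these differences was tested.

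Replicated peaks lay mostly in introns, and gene starts held the largest excess over shuffled peaks. Of the 83483 peaks, 13.9% had their middle within 1 kb of an annotated 5′ end, 6.33% lay in exons, 55.5% in introns and 24.3% between genes. The corresponding shares of the replicates were 11.97% ± 0.989, 6.08% ± 0.496, 56.6% ± 1.29 and 25.4% ± 2.78 (SD, n = 2). Against peaks shuffled within chromosomes, start sites held 3.49 times as many, exons 1.53 times, introns 1.31 times and the space between genes 0.490 times (two-sided permutation p = 0.0198 for each, the smallest that 100 shuffles can give). Of 21728 protein-coding genes, 10111 (46.5%) had a replicated peak within 1 kb of the 5′ end and 13999 (64.4%) within 10 kb. With the distance widened to 2 kb, 24.8% of replicated peaks counted as start-site peaks.

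Around the 5′ ends of protein-coding genes the peaks flanked the start and were sparse on it. Averaged over the replicates, coverage reached 13.5% ± 8.36 of genes at 600 bp upstream, dropped to 5.48% ± 3.18 at 100 bp downstream and rose to 21.2% ± 9.68 at 1100 bp downstream (SD, n = 2). Both replicates had this shape, with downstream maxima of 28.1% and 14.4%. Genes were also split by quintile of CpG content at the 5′ end, measured as observed over expected CpG. The top quintile had replicated peaks over 1.43% of starts but over 48.7% of positions 1300 bp downstream. In the bottom quintile coverage lay between 0.942% and 2.19% over the 5 kb on each side. A replicated peak lay within 10 kb of 93.1% of the genes in the top quintile and of 19.03% in the bottom one.

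**Figure D1:**
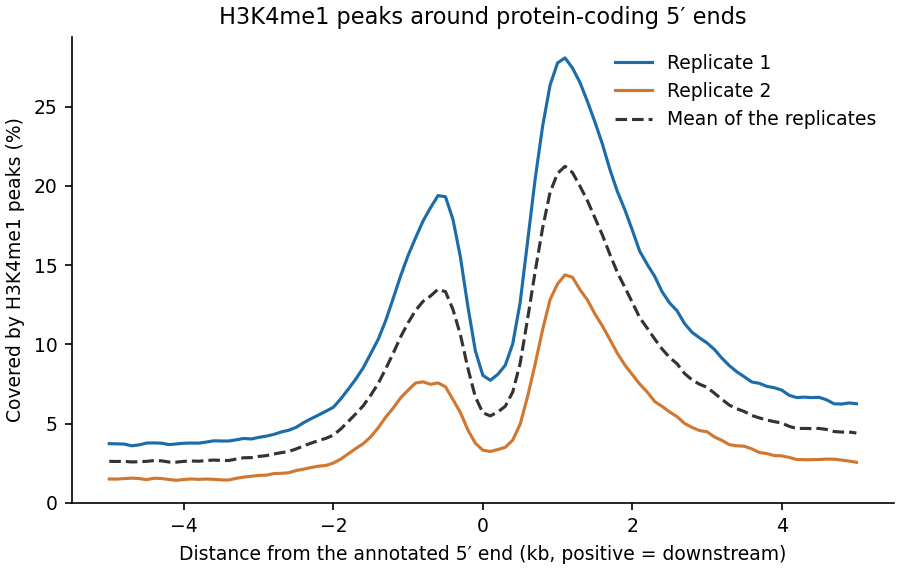
Percentage of protein-coding genes covered by H3K4me1 peaks (vertical axis) by distance from the annotated 5′ end in kb (horizontal axis, positive downstream), as a line for each replicate and a dashed line for their mean. Both replicates dip at the start, to 7.73% and 3.24%, between an upstream and a higher downstream maximum.

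Genes were then compared by their window share. Hoxa4, a homeobox gene of axial patterning on chromosome 6 (52189671 to 52191753), had the largest mean, at 65.0% ± 17.1 in the replicates (SD, n = 2) and 80.9% in replicated peaks. Rara, the retinoic acid receptor alpha on chromosome 11 (98927818 to 98974942), followed at 58.2% ± 9.34. Bahcc1 (chromosome 11, 120232947 to 120292296) stood at 57.8% ± 8.17, and Ctdsp2, a phosphatase gene (chromosome 10, 126978717 to 126999975), at 52.6% ± 14.3. Nr1d1, a nuclear receptor of the circadian clock (chromosome 11, 98767932 to 98775333), had 52.2% ± 9.64, and the transcription factor gene Mef2d (chromosome 3, 88142372 to 88172086) had 51.0% ± 6.70. Glis2, Kif21b, Tgfbi and Pcdhgc5 completed the first 10, between 50.9% and 49.9%. Glis2 encodes a zinc finger transcription factor, Tgfbi an extracellular matrix protein and Pcdhgc5 a gamma protocadherin. The median protein-coding gene had 5.27% in replicate 1, 1.57% in replicate 2 and 3.605% in replicated peaks.

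Each of 23 gene lists was described by the median window share of its members in replicated peaks and by that median's place among 10000 random lists of as many protein-coding genes. These p values, adjusted over the 23 lists by the Benjamini-Hochberg method, describe these samples, since genes are not replicates. Random lists were drawn gene by gene. For lists of neighbours with overlapping windows, such as Hox genes, p values can therefore be too small. The median lay above random lists for 8 lists and below for 1, and the other 14 did not pass at 0.05. Random lists had medians near 3.6%. The lower bound of their central range was 0% for every list except olfactory receptors, where it was 3.1%. No median can lie under 0%, so the lists other than olfactory receptors could pass above random lists but not below. For these lists, a result that did not pass therefore says nothing about low coverage.

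Genes of the gut mesenchyme, the tissue that forms the connective layers of the wall, were among the covered lists. All 28 had a replicated peak in the window, and their median was 11.2% (adjusted permutation p = 0.00276), with list medians of 11.1% ± 8.32 in the replicates (SD, n = 2). The call was lost in windows of 2 kb each side (adjusted permutation p = 0.518). Pdgfrb, a receptor of platelet-derived growth factor on pericytes and fibroblasts (chromosome 18, 61045150 to 61085061), stood at 40.3% ± 14.8. Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042), had 33.3% ± 14.2, Hand1 31.4% ± 17.7 and Hlx, a homeobox gene of the visceral mesenchyme, 24.4% ± 17.1. Foxf1, a target of hedgehog signals in gut mesenchyme, had 12.3% ± 9.36. The list for smooth muscle and interstitial cells of Cajal, the pacemaker cells of the gut, had a median of 8.51% and a peak at 20 of 21 members (adjusted permutation p = 0.0383). Its leading members were Actn1 (alpha-actinin, 27.8% ± 17.4), Tpm1 (tropomyosin, 23.4% ± 6.39), Srf (serum response factor, 20.8% ± 4.28) and Ano1 (a chloride channel of interstitial cells of Cajal, 19.1% ± 8.88). This call was lost in 6 of 13 alternatives, among them another draw of random lists (adjusted permutation p = 0.0572).

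The other lists for cells of the gut wall did not pass above random lists, and with a lower bound of 0% they could not pass below. Gut epithelium had a median of 4.80% with a peak at 24 of 30 members (adjusted permutation p = 0.536), and it passed in replicate 1 alone, at 9.43% (adjusted permutation p = 0.0465). Cdx1, an intestinal homeobox gene (chromosome 18, 61018862 to 61036199), had 26.2% ± 11.4, and the keratin genes Krt8, Krt19 and Krt18 had 16.8% ± 10.7, 14.7% ± 10.4 and 13.3% ± 8.56. The window of Cdx1 overlaps that of Pdgfrb of the mesenchyme list, so the values of these genes are not independent. Cdx2, the paralogue of Cdx1, had 3.07% ± 4.35, and Isx had no peak in either replicate. Genes of the enteric nervous system had a median of 2.20% with a peak at 14 of 23 members (adjusted permutation p = 0.536). Gfra1, the co-receptor of the neurotrophic factor GDNF, had 13.5% ± 5.58, Ednrb 11% ± 7.14, Hand2 10.6% ± 10.8 and Phox2a 9.47% ± 3.16, while Plp1 and Vip had no peak in either replicate. Blood and lymphatic endothelium had 5.01% (adjusted permutation p = 0.554), led by Fli1 (20.8% ± 14.4) and Eng (20.8% ± 11.1), with no peak at Tie1. Mesothelium had 2.81% (adjusted permutation p = 0.8005), led by Wt1 (10.6% ± 8.13), with no peak at Muc16 and Gpm6a.

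Signalling pathways that pattern the gut were covered throughout. Every one of the 16 Notch genes had a replicated peak, with a median of 20.6% (adjusted permutation p = 0.00153, from the smallest p that the random lists can give). The targets Hes1 (chromosome 16, 30064384 to 30067796) and Heyl had 25.02% ± 10.3 and 23.7% ± 12.3, and the receptor gene Notch1 and the modifier gene Lfng had 22.6% ± 10.4 and 20.3% ± 7.03. All 18 Wnt genes had a peak, with a median of 14% (adjusted permutation p = 0.00153). Tcf7l2, the transcription factor of Wnt signalling in the intestine (chromosome 19, 55741820 to 55933654), had 29.4% ± 8.23, the feedback gene Axin2 24.3% ± 21.3, Wnt11 18.9% ± 10.5 and Sfrp1 16.3% ± 11.2. The 24 BMP and TGF-beta genes had a median of 11.2% (adjusted permutation p = 0.00276), a call lost in windows of 50 kb (adjusted permutation p = 0.0736) and of 2 kb each side (adjusted permutation p = 0.196). The BMP target genes Id1 (chromosome 2, 152736251 to 152737410) and Id3 had 39.9% ± 13.2 and 37.8% ± 14.3, the inhibitor gene Smad7 36.2% ± 12.7 and the ligand gene Bmp7 29.2% ± 11.5. The 14 hedgehog genes had a median of 10.2% (adjusted permutation p = 0.0383), a call lost in 8 of 13 alternatives, with replicate 2 alone at 3.05% (adjusted permutation p = 0.503). Gli3, a transcription factor of the pathway (chromosome 13, 15463235 to 15730026), had 22.2% ± 14.2, Sufu 17.4% ± 8.998, Boc 17.4% ± 16.2 and Gli2 16.8% ± 8.80.

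Housekeeping genes, which nearly all cells use, lay above random lists and olfactory receptor genes below. The housekeeping median was 12.4% with a peak at 15 of 16 members (adjusted permutation p = 0.00328), led by Polr2a at 23.3% ± 10.3 and Actb at 18.1% ± 4.49. The 1092 olfactory receptor genes, which are used in the nose, had a median of 0% and a replicated peak at 16 members (adjusted permutation p = 0.00153, below random lists). Their highest mean was 3.92% ± 0.177 at Olfr279, and Olfr1, Olfr10 and Olfr1000 had no peak. With random lists matched on CpG content the olfactory call was lost (adjusted permutation p = 1). That comparison cannot decide, because the median gene of the bottom CpG quintile also had 0%, which leaves no room below. A replicated peak lay in the window of 1.465% of the receptors, against 19.03% of coding genes in that quintile. The difference of these shares was not tested. In windows of 2 kb each side of the 5′ end 2 lists passed above random lists, Notch and Wnt, and at a fold of at least 3 there were 5.

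Lists for other organs and for differentiated cells did not pass above random lists, and with a lower bound of 0% they could not pass below. Forebrain genes had a median of 5.16% (adjusted permutation p = 0.536), with Bcl11b at 11.5% ± 11.1, Emx1 at 11.2% ± 3.68 and no peak at Otx2. Heart genes had 3.88% (adjusted permutation p = 0.896), led by the myosin light chain genes Myl3 at 30.9% ± 17.0 and Myl7 at 18.5% ± 11.1, with no peak at Myh6, Myl2 and Nppb. Skeletal muscle had 2.67% (adjusted permutation p = 0.722), led by Tnnc2 at 11.6% ± 6.03, and pancreas 1.67% (adjusted permutation p = 0.536), led by Cpa1 at 16.6% ± 5.53, with no peak at Ins1, Ins2 and Cel. Retina had 0.797% (adjusted permutation p = 0.402), led by Opn1sw at 8.12% ± 3.66, with no peak at Crx. Mature intestinal epithelial lineages had 0.615% (adjusted permutation p = 0.252), led by Pou2f3 of tuft cells at 9.81% ± 4.68 and Spdef of goblet cells at 8.34% ± 1.38, with no peak at Muc2, Lyz1 and Lct. Lung and stomach had 0.562% (adjusted permutation p = 0.252), led by Foxj1 at 17.3% ± 6.95 and Sftpc at 16.9% ± 13.5. Blood cells, liver and germ cells had medians of 0% (adjusted permutation p = 0.252, 0.252 and 0.445). Cd68 of macrophages had 10.7% ± 7.84, Arg1 of the liver list 4.64% ± 5.16 and Nobox of the germ cell list 5.40% ± 3.87. Ptprc, the gene of the leukocyte antigen CD45, and Alb, the albumin gene, had no peak in either replicate.

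**Figure D2:**
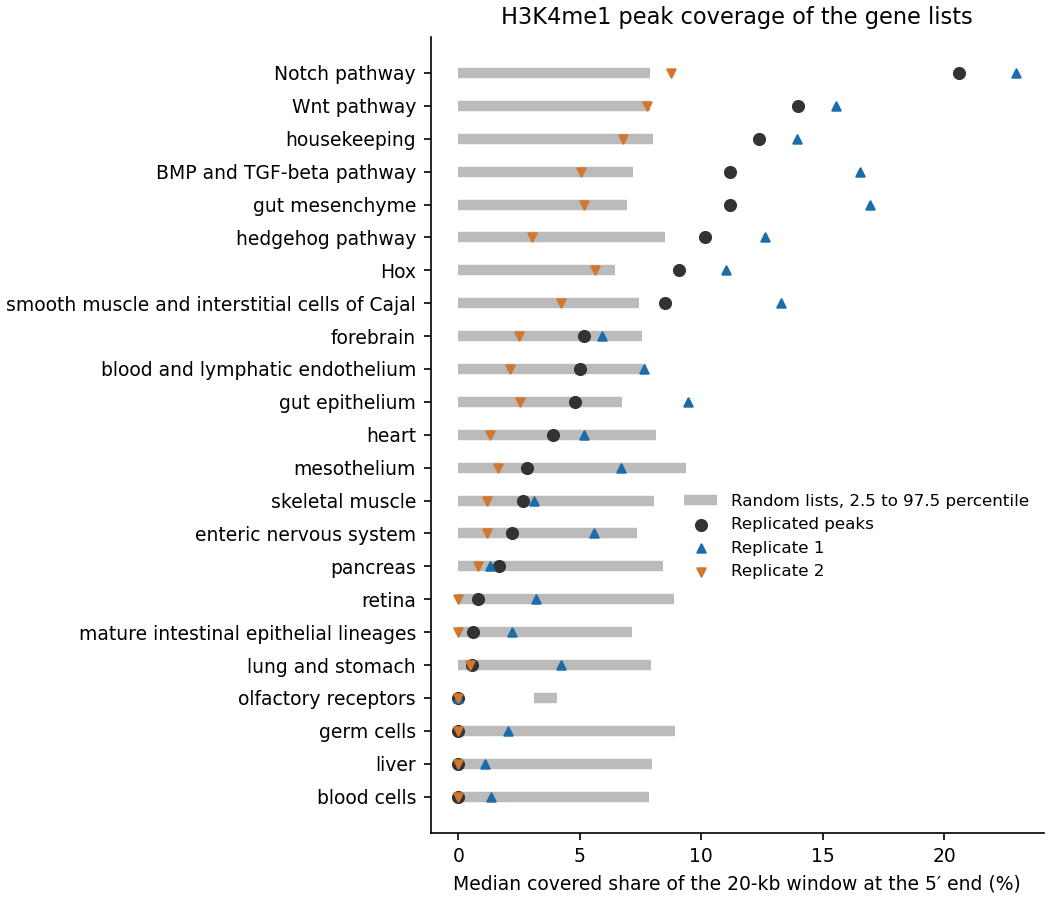
Median percentage of the 20-kb window at the 5′ end covered by H3K4me1 peaks (horizontal axis) for the 23 gene lists (vertical axis), in replicated peaks (circles) and in each replicate (triangles), with grey bars for the central 95% of random lists in replicated peaks. The circles of 8 lists lie right of the bars, from Notch at 20.6% to smooth muscle and interstitial cells of Cajal at 8.51%, and olfactory receptors lie left.

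Pooled over genes, the lists for cells of the gut wall had more coverage than those for other organs, but not list by list. Gut mesenchyme and smooth muscle had medians of 11.2% and 8.51%, while the 4 gut lists that did not pass had 2.20% to 5.01%, all below the 5.16% of forebrain, with the enteric nervous system and mesothelium also below the 3.88% of heart. The classes were not compared without mesenchyme and smooth muscle. The median window share was 6.32% over 131 genes of the gut class and 1.74% over 129 genes of other organs. The list of mature intestinal epithelial lineages, with a median of 0.615%, was in neither class. The difference was 4.58 percentage points (two-sided permutation p = 2e-05). It was 6.01 points in replicate 1 (permutation p = 1e-05, the smallest that 100000 permutations can give) and 1.77 points in replicate 2 (permutation p = 1e-04). Windows of 2 kb each side gave 11.8 points (permutation p = 0.00038) and windows of 50 kb gave 1.77 (permutation p = 0.00034).

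Hox genes have paralogue groups that are expressed in order from the front to the rear of the body axis. In clusters A, B and C they were covered more toward the low-numbered end, although Hoxb1 had only 11.1% in replicated peaks. All windows measured in cluster D were low. The order of the groups was not tested. Groups 1 to 4 had a median window share of 36.4% over 12 genes, all with a replicated peak, although the members of cluster D had at most 10.7%. There Hoxd3 and Hoxd4 had 2.78%, against 2.92% at Hoxd12 and 4.01% at Hoxd13. The windows of Hoxd3 and Hoxd4 lie next to Hoxd8, and most of the stretch between these windows and Hoxd1 was not measured. Groups 5 to 9 had 11.3% over 15 genes, and groups 10 to 13 had 0.777% over 12 genes, 6 of them without a replicated peak. The replicates' medians were 39.0% and 17.0% for groups 1 to 4, 18.1% and 8.07% for groups 5 to 9, and 4.39% and 0% for groups 10 to 13. As a list, the 39 Hox genes had 9.07% (adjusted permutation p = 0.00307), a call lost in 3 of 13 alternatives. Random lists do not model the overlap of windows within the Hox clusters, so this p can be too small. In windows of 2 kb each side the list's median of 8.65% lay under the random median of 8.97% (adjusted permutation p = 0.946), and groups 5 to 9 had 0.650%, while groups 1 to 4 had 36.6%. Windows of 50 kb each side gave 23.2% for groups 5 to 9 and 4.16% for groups 10 to 13, and equal numbers of peaks gave 20.1% for groups 1 to 4.

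By cluster, HoxA had a median of 33.0% in replicated peaks, HoxB 16.6%, HoxC 1.56% and HoxD 2.78%. Hoxa5 had 45.0% ± 20.6, Hoxb2 38.2% ± 8.34, Hoxb3 36.5% ± 18.2 and Hoxb5 36.4% ± 13.96 (SD, n = 2). In the HoxC cluster Hoxc4 had 22.3% ± 10.5 and Hoxc6 21.6% ± 17.8, and in the HoxD cluster Hoxd1 led at 8.26% ± 2.54. Hoxa9, Hoxa10 and Hoxa11 had 1.82% ± 2.57, 0.552% ± 0.781 and 0.552% ± 0.781, Hoxa13 had 4.72% ± 4.30, and Hoxc12 and Hoxc13 had no peak in either replicate. Windows of neighbouring Hox genes overlap, so their values are not independent. Hoxc5 has its outermost annotated 5′ end beside that of Hoxc10, and Hoxd3 and Hoxd4 have theirs 2 bp apart, so these windows were in effect shared. The outermost end of Hoxd3 and Hoxd4 lies next to Hoxd8, and that of Hoxa3 between those of Hoxa6 and Hoxa7. The values of these 4 genes therefore describe those parts of the clusters. They were kept in the medians of their paralogue groups, which were not recomputed without them. The median of 36.4% for groups 1 to 4 lies midway between Hoxa1 (33.0%) and Hoxa3 (39.8%).

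**Figure D3:**
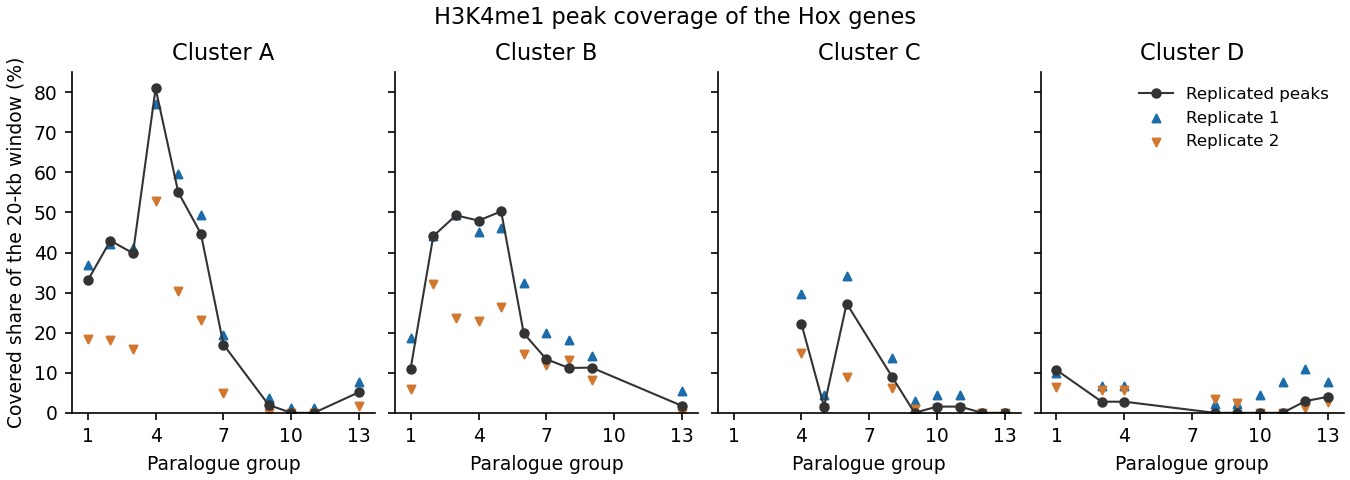
Percentage of the 20-kb window covered by H3K4me1 peaks (vertical axis) for each Hox gene by paralogue group (horizontal axis) in clusters A to D, in replicated peaks (joined circles) and in each replicate (triangles). Coverage peaks at Hoxa4 with 80.9% in cluster A and at Hoxb5 with 50.3% in cluster B, and groups 10 to 13 stay at or below 5.17% in replicated peaks.

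Over the HoxA cluster, a region of 145 kb on chromosome 6 (52135590 to 52280880), replicate 1 listed 76 peaks over 39.9 kb and replicate 2 listed 43 over 20.04 kb. The replicated list held 48 peaks there, over 37.7 kb.

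**Figure D4:**
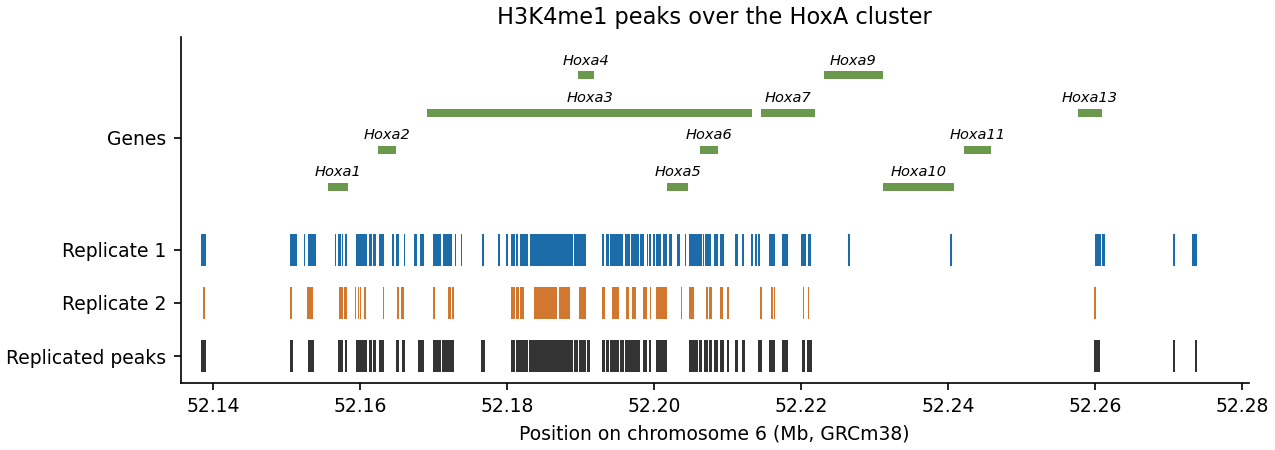
H3K4me1 peaks of each replicate and replicated peaks (bars to scale) along the HoxA cluster, with gene bodies above and the position on chromosome 6 in Mb (GRCm38) on the horizontal axis. The peaks are dense from Hoxa1 to Hoxa7 and nearly absent from Hoxa9 to Hoxa11, with 48 replicated peaks in the region.

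Replicated peaks joined across gaps of up to 3 kb formed 44323 domains, of which 972 spanned at least 10 kb. The longest, of 67.2 kb on chromosome 8 (120484648 to 120551895), lay over Gse1, which shares the locus with the annotated gene Gm20388, and peaks covered 38.0 kb ± 11.7 of it in the replicates (SD, n = 2). The next spanned 55.8 kb at Hmga2, a chromatin protein gene of fetal growth (chromosome 10, 120383882 to 120439678), with 29.9 kb ± 10.5 covered. A domain of 52.5 kb lay at Pmepa1, an inhibitor gene of TGF-beta signalling (chromosome 2, 173224897 to 173277365). One of 52.3 kb lay at Tcf7l1, a transcription factor gene of the Wnt pathway (chromosome 6, 72647839 to 72700103). The domain over Cdc6 and Rara spanned 49.3 kb (chromosome 11, 98922619 to 98971908), and one over Fgfr2 and Ctbp2 spanned 49.7 kb. Shb, Zfhx3, Map4k4 and Ski held the remaining domains of the first 10, with 44.7, 43.0, 42.5 and 41.5 kb, Ski being a repressor of TGF-beta signalling. The number and the order rest on the joining rule and the list. Domains of at least 10 kb numbered 110 with gaps of up to 1 kb and 5519 with gaps of up to 10 kb, against 2252 in replicate 1 and 548 in replicate 2.

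The replicated peaks with the largest fold enrichment had their point source in introns, with 1 exception, when start sites were not set apart. The first had a fold of 9.79 and spanned 3796 bp in an intron of Lasp1, an actin-binding protein gene (chromosome 11, 97803582 to 97807377), where the replicates' peaks covered 3628 bp ± 233 (SD, n = 2). Introns of Ccdc85c (chromosome 12, 108244348 to 108246025) and Zmiz1, a transcriptional coactivator gene (chromosome 14, 25462622 to 25464695), held the next, with folds of 9.38 and 9.18. Grk2, a kinase gene of G protein-coupled receptors, had 9.05 in an intron (chromosome 19, 4300139 to 4305437). A peak between genes on chromosome 11 (94988156 to 94989508), 1971 bp upstream of the 5′ end of Ppp1r9b, and an intronic peak of 7604 bp in the histone deacetylase gene Hdac5 both had 9.02. Introns of Zfp608 (8.87), Cpsf7, Zfp618 and Capzb (8.72 each) held the rest of the first 10. The point source in Cpsf7 lay 366 bp upstream of the 5′ end of Sdhaf2, within the start-site distance of 1 kb. Both replicates had peaks at all 10.

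Chromosome X held few peaks. Replicated peaks numbered 1.87 per Mb on X, against a median of 34.8 per Mb over the autosomes and a range from 25.3 on chromosome 14 to 53.3 on chromosome 11. X had 8.69 per Mb in replicate 1 and 1.69 in replicate 2, with autosome medians of 75.8 and 35.9. The ratio of X to the autosome median was 0.0536 in replicated peaks, 0.115 in replicate 1 and 0.0471 in replicate 2, a mean of 0.0808 ± 0.0478 (SD, n = 2). Of the coding genes on X, 2.64% had a replicated peak within 1 kb of the 5′ end, against a median of 47.4% over the autosomes. The replicates had 15.7% and 2.32% there, with autosome medians of 60.06% and 37.35%. The X genes with the largest mean window share were chosen after the data were seen. They were Bcor, a corepressor gene (chromosome X, 12036740 to 12160355, 14.7% ± 11.8), Tmem164 (10.3% ± 13.01), Gpc3, a glypican gene (9.89% ± 5.64), Bgn, the biglycan gene (9.04% ± 9.56), and Efnb1, an ephrin gene (8.72% ± 7.31).

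**Figure D5:**
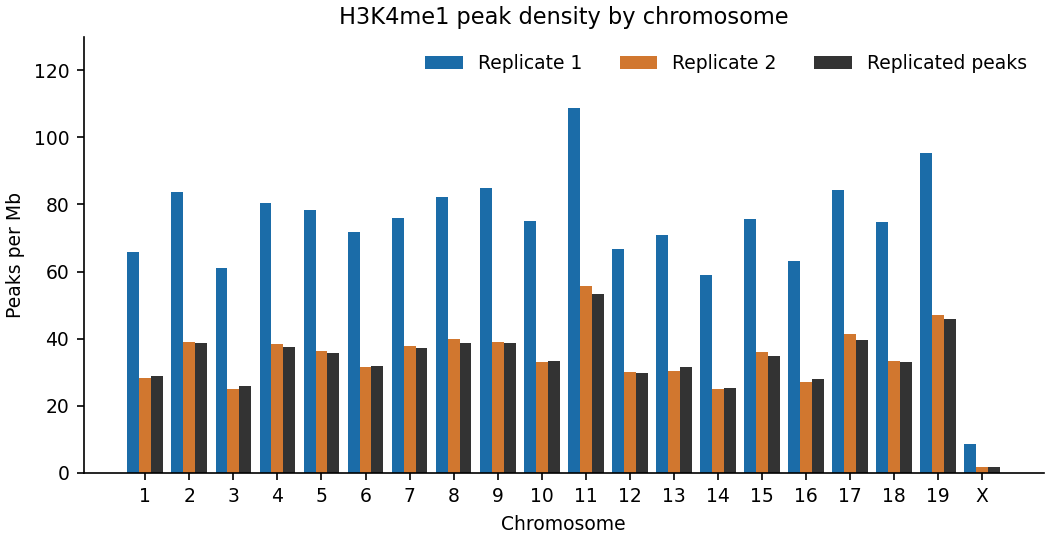
H3K4me1 peaks per Mb outside assembly gaps (vertical axis, from 0) on each autosome and on X (horizontal axis), as bars for each replicate and for replicated peaks. X stands at 8.69, 1.69 and 1.87 per Mb, below every autosome, and chromosome 11 is the highest.

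Consensus sites of 20 transcription factor families were counted in the 500 bp around the point source of 71881 distal replicated peaks, and in windows outside peaks matched on chromosome and GC content. The NFI palindrome TTGGCNNNNNGCCAA was present at 0.189% of peaks and 0.0284% of background windows, a ratio of 6.67. The MEF2 site, bound by muscle regulators, had a ratio of 2.06, and the HNF1 site of gut epithelial regulators 1.81. The forkhead site TGTTTAC, bound by FOX factors, was present at 9.98% of peaks and 5.72% of windows, a ratio of 1.75. CTCF had 1.61, TEAD 1.45, ETS 1.42 and the site of posterior Hox proteins (HOX13) 1.39. HNF4 (1.22), RUNX (1.21), AP-1 (1.18), GATA (1.18), REST (1.17), the CArG box of serum response factor (1.15), MEIS (1.11), CRX (1.09), CDX (1.06) and the E-box of HAND and TWIST (1.01) had smaller ratios above 1. Sites of SOX and Oct factors were less frequent, at ratios of 0.837 and 0.905. Each of the 20 had an adjusted permutation p of 0.0198, the smallest that 100 draws of background windows can give. With background windows 5 to 10 kb from the peak the Oct ratio turned to 1.12 and REST no longer passed (1.05, adjusted permutation p = 0.297). The Oct call was also lost at a fold of at least 3 (adjusted permutation p = 0.0594). With windows of 1000 bp the E-box ratio turned to 0.991, and it did not pass in replicate 2 alone (adjusted permutation p = 0.0792) or in pooled peaks overlapping both replicates (adjusted permutation p = 0.0594).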

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

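The alternatives with pooled peaks overlapping both replicates, with autosomal genes only and with another draw of random lists were chosen after the data were seen, and the others before. For results that answer a comparison, 95 values under alternatives stayed within their limits and 27 moved. For single lists and motifs, 410 kept their side of the threshold, and those that had passed also kept their direction. Another 25 lost significance, 1 gained it and 3 that had passed reversed. A change of direction in a list that had not passed was not counted. The difference between gut and other-organ classes stayed positive and past its threshold in all 11 alternatives (1.77 to 11.8 points), as did the excess of start-site peaks in 8 (10.2% to 24.8%). Notch and Wnt genes passed in all 13 alternatives. The cause of the changes below was not tested unless it follows from the setting. Fewer peaks follow by construction from joining across 1 kb (101515 in replicate 1, 54465 in replicate 2) and from the q limit of 0.01 in replicate 2 (26222). Lists above random lists numbered 5 at a fold of at least 3 and 2 in windows of 2 kb each side. Lists below numbered 0 with CpG matching, where the olfactory receptor median of 0% had no room to lie below. In windows of 2 kb each side the Hox list reversed to a median of 8.65%, below random lists at 8.97% (adjusted permutation p = 0.946), and paralogue groups 5 to 9 had 0.650%. Windows of 50 kb each side gave 23.2% for groups 5 to 9 and 4.16% for groups 10 to 13. Equal numbers of peaks gave 20.1% for groups 1 to 4, from shares averaged over the replicates rather than from replicated peaks. Domains of at least 10 kb numbered 110 with gaps of up to 1 kb, 5519 with gaps of up to 10 kb and 575 with pooled peaks overlapping both replicates. The longest domain was 27.5 kb and 256 kb with these gaps, and 2, 3 and 6 of the 10 longest domains overlapped one of the 10 longest in these settings. Motifs less frequent than background numbered 1 at a fold of at least 3 and 1 with background windows 5 to 10 kb from the peak, where the Oct ratio reversed to 1.12. In windows of 1000 bp the E-box ratio reversed to 0.991. With each replicate left out in turn, groups 1 to 4 ranged from 17.0% to 39.0%, groups 10 to 13 from 0% to 4.39%, domains of at least 10 kb from 548 to 2252, the longest domain from 66.97 to 74.4 kb, the overlap of the 10 longest from 4 to 7, and the ratio of X to autosomes from 0.0471 to 0.115. Without replicate 2 the gut epithelium list gained significance (9.43%, adjusted permutation p = 0.0465), and without replicate 1 the hedgehog list lost it (3.05%, adjusted permutation p = 0.503). No paired analysis was possible because there is 1 group. The lists give no read numbers, and no alternative changed the read depth.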

Other observations

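The tests of gene families, of read depth and of a halved signal were chosen after the result was seen, and the other tests before. Gene families were formed from the letters that open a symbol, 334 families of 8 to 200 coding genes, and tested like the lists, against 10000 random lists each with adjustment over the families. The median window share lay above random lists for 15 families at an adjusted permutation p under 0.05, and below for 0. These random lists were not matched on CpG content, so its part in the calls was not tested. The median coding gene had 7.52% in the top CpG quintile and 0% in the bottom one. Beside Hoxa (33.0%) and Hoxb (16.6%), the myosin light chain genes (Myl) had 20.9% with a peak at 8 of 11 members, the signal transducers of the TGF-beta family (Smad) 19.2% at 8 of 8, and symbols that open with Irf, mostly interferon regulatory factors but also genes of their binding partners, 17.8% at 12 of 12. Smad3 (chromosome 9, 63646767 to 63757994) had 28.7% ± 18.6 in the replicates and Irf1 (chromosome 11, 53770014 to 53778374) 25.3% ± 4.27 (SD, n = 2). Histone genes (Hist) had 14.01% with a peak at 59 of 67 members, many of them neighbours with overlapping windows. Windows also overlap within Hoxa and within Hoxb. The random lists do not model such overlap, so the p values of these families can be too small. Symbols that open with Rps and Rpl had 8.24% and 7.79%. They are mostly ribosomal protein genes, and Rps also takes in kinases of the ribosomal protein S6. The family of Zbtb transcription factors had 9.97%. The families Abhd, Tspan, Arhgef, Bcl, Ppp and Rab also passed, with medians from 8.27% to 13.8%. These medians are those of replicated peaks. In replicate 2 alone Myl had 10.7%, Smad 12.9%, Irf 8.46%, Hist 5.11% and Tspan 3.815%, where the median coding gene had 1.57%, and the families were not tested in single replicates. No member of Defa, Mup, Serpina or Rhox had a replicated peak, which families of that size cannot bring past the threshold (adjusted permutation p = 0.408, 0.408, 0.408 and 0.369).

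The clustered protocadherins, cell surface proteins that neurons choose from alternative first exons, were split. All 3 C-type members of the gamma cluster had replicated peaks, Pcdhgc3 over 29.9% of the window, Pcdhgc4 over 55.8% and Pcdhgc5 over 60.5%, with 24.97% ± 10.9, 44.2% ± 9.37 and 49.9% ± 10.6 in the replicates (SD, n = 2). Their gene bodies lie on chromosome 18 between 37806364 and 37841873, with overlapping windows. A replicated peak was present at 1 of 13 Pcdha genes, with 2.5% of its window. That gene was not among the 11 named Pcdha and a number, of which 0 had a replicated peak. The same held for 0 of 22 Pcdhb, 0 of 12 Pcdhga and 0 of 6 Pcdhgb genes. The difference was not tested.

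Replicate 2 listed 84066 peaks and replicate 1 listed 183305. The background recovered from the fold and p values before scaling was 2.78 extended reads per position in replicate 2 and 2.26 in replicate 1, a ratio of 1.23, and the shortest peak was 195 bp in both. A lower read depth of replicate 2 would have given a ratio below 1. The pileups and backgrounds of replicate 1 were then multiplied by the scale of replicate 2 (0.765). At the point source 179236 peaks kept a p of 0.01 or lower, 2.13 times the number of replicate 2. The count can be too high, because a narrowing of peaks below the shortest listed width was not modelled. On its own the count therefore cannot decide whether the scaling is the whole cause. After scaling, the recovered background was 2.13 in replicate 2 and 2.26 in replicate 1. Scaling thus left replicate 2 close to replicate 1, which argues against it as the whole cause. A weaker enrichment in replicate 2, its control, or a difference between the embryo pools may account for the gap, and these were not tested, nor was any biological explanation, since there is 1 group.

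Chromosome X had 1.94 replicated peaks per Mb in bins of 1 Mb. Autosomal bins matched on coding genes and repeats had 13.3 per Mb, with 8.26 as the lowest of 1000 bootstrap means, which argues against gene and repeat content as the whole cause. When the autosomal pileups were also halved in a simulation, replicate 1 kept 12.5 peaks per Mb in the matched bins, 1.38 times the 9.02 on X, with bootstrap means from 8.03 to 17.8. Replicate 2 kept 3.58 per Mb, 2.02 times the 1.77 on X, with bootstrap means from 1.94 to 5.19, all above X. The limit set for a fit was met by replicate 1 and exceeded by replicate 2. Only the pileup at the point source was halved and peak width was not modelled, so the numbers kept can be too high. The background of each peak was left unchanged. If the control signal is also lower on X, the numbers kept can instead be too low. Both limits apply to each replicate. In replicate 2 a halved signal and a larger loss therefore cannot be told apart. A candidate explanation, as a hypothesis, is a single X copy in male embryos and a mostly silent second copy in females of the mixed pools, which these lists do not separate by sex. Lists from separate male and female pools, or reads assigned to the X alleles, would test it.

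Of the replicated peaks, 29767 lacked a peak of at least 1 replicate, 26310 of them with a peak in replicate 1 only and 1064 with none. Shifted boundaries would bring a peak of both replicates within 500 bp, and this held for 27.7% of them, against 4.32% for shuffled peaks, short of the 50% set as the limit. Selection by the pooled p value alone would let a single limit on p sort the pooled peaks without an overlap in both replicates, and the best limit placed 74.7% correctly, against 65.95% from the larger class alone. Of 34291 pooled peaks covered to at least 50% in both replicates, 34284 were replicated peaks. A rule that also admits overlap with peaks of split pools, lists not used here, may account for the rest and was not tested.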
